A study of Drosophila melanogaster with 2 samples.

How the data were processed

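The series holds transcription factor ChIP-seq of Glass, the protein of the gene gl, from whole Drosophila melanogaster pupae. Per the labels, the flies carried a transgene for Glass with GFP at its C terminus, males and females were pooled, the pupae were 24 hour old, and chromatin was sheared by sonication to between 200 and 800 bp. The labels give 2 biological replicates of 1 group, with their numbers, and no other condition. The free-text description of both samples speaks of an input control, whereas the antibody field, the assay name and the peak files describe ChIP of gl, and the samples were treated as ChIP throughout.

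Peak lists were deposited for the dm6 build: a list for each replicate, a list from the pooled replicates, and a list that the authors thresholded by the irreproducible discovery rate, called the optimal list here. Per the deposited text files, each replicate list was derived from the alignment of that replicate and an alignment of a control shared by both replicates, and the optimal list from the replicate and pooled lists. The height of each peak is the authors' signal value, and its significance is a −log10 q value of the authors, both deposited in the lists. The column for a p-value holds no value and was not used here. The aligner, the peak caller and the number of reads were not given in the sources used here, so the depth behind the peaks is unknown, and no interval below covers read counting.

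Each replicate list and the pooled list had 30000 entries, and the optimal list had 4809. All 4809 optimal peaks were the 4809 strongest entries of the pooled list, so that taking these from the pooled list gives the same peaks by construction. All optimal peaks had the highest −log10 q value of the list, 4.10, so that peaks were ranked by signal value. In the optimal list 56.7% of the peaks had the same width, 390 bp. No entry had the same interval and signal value in both replicate lists. Signal values were used to rank and describe peaks within a list. Because the replicates enter the optimal list together, most results were also computed on the 4809 strongest peaks of each replicate list. Matching on TSS count and the comparison of tRNA genes with protein-coding genes used the optimal list alone.

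Genes and transcription start sites (TSSs) came from Ensembl release 115 for BDGP6.54, the assembly also known as dm6, and sequence from the same assembly at NCBI. Analyses covered the arms 2L, 2R, 3L, 3R, 4 and X, with 13945 protein-coding genes. Coordinates are 1-based. Peaks of the replicates were called shared when their summits lay within 200 bp, and their number was compared with 1000 circular shifts of the summits along each chromosome. The share of summits within 1 kb of a TSS of a protein-coding gene was compared with 1000 such shifts, and the median signal at TSSs with the others by a permutation test with 100000 resamples. The density of peaks on X was compared with that on 2L, 2R, 3L and 3R by an exact binomial test. A gene was called bound when a summit lay in its span extended by 1 kb to both sides. For each of 13 gene lists the number of bound members was compared with 10000 random lists matched on the length of the span in 20 bins, and the median signal of the strongest peak of its bound members was given as a percentile among 10000 matched lists of bound genes. A summit could count for more than 1 neighbouring member of a list, and the random lists were not matched on such sharing. The interval of the correlation came from 1000 bootstrap draws of peaks. The frequency of each 6-mer, with both strands joined, within 50 bp of the summits was compared with windows 500 bp to one side of the same peaks by an exact McNemar test, and a 6-mer was called at an adjusted p under 0.05 and a fold of at least 1.5. All permutation tests were two-sided, and p-values of lists and 6-mers were adjusted by the method of Benjamini and Hochberg. Peaks and genes are not independent replicates, and these p-values describe the peak lists, not the spread between animals.

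The gene lists, 7 fixed motifs, tests and most alternatives were chosen before the data were examined. The lists held genes of retinal specification, phototransduction and the rhabdomere, lens, cone and pigment cells, the ecdysone response, Notch and EGFR signalling, body patterning, neurons, glia, muscle, fat body and blood cells, the male and female germ line, cuticle proteins and ribosomal proteins. For 5 genes the listed symbol was replaced by that of the annotation. Genes are named by a rule set with the tests: gl, the genes nearest to or holding the 15 strongest optimal peaks, up to 3 members of each list with the strongest peaks, the 10 genes with the most summits, and up to 10 called 6-mers with the largest fold beside the fixed motifs.

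The tests were checked on simulated peaks, 4809 in each set. These were circular shifts of the optimal summits, or random draws of chromosomes for the X ratio. The 6-mer test called 17 of 20 6-mers planted at 4% of the summits and 0 of the other 2060. Shifted summits have no built-in difference in sequence from their flanks, so false calls at the real summits were not measured. The list test called 5 of 5 lists with a summit put in 80% of the members and 0 of 20 untouched lists. The TSS test called 20 of 20 sets with 20% of the summits moved to a TSS and 5 of 100 sets with none moved. An overlap of 60% was measured as 61.1%, and a planted X to autosome ratio of 1.3 as 1.30 ± 0.0471 (SD over 100 draws). The alternatives were other distances, windows and numbers of peaks, the stronger peaks alone, each replicate left out, and other definitions of a bound gene. An explanation was set aside in the closing section only where its value lay on the other side of a bound with its 95% interval clear of the values the explanation needs. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.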

Results

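Binding of GFP-tagged Glass, a zinc finger transcription factor required for photoreceptor development, was mapped by ChIP-seq in whole pupae in 2 biological replicates. The optimal list held 4809 peaks, with signal values from 127.0 to 3648 and a median of 200.4. Of 13945 protein-coding genes, 3224 (23.1%) had a summit within their span extended by 1 kb, and 157 genes had 5 or more. With 1 group, the replicates are the only samples that can be compared with each other.

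The gl gene itself (FBgn0004618, 3R 18367927 to 18372738, minus strand) held 2 summits of the optimal list within its extended span. The stronger lay in an intron at 18371512, with a signal value of 267.5 and rank 1537 of 4809, and it ranked 1812 in the list of replicate 1 and 1604 in that of replicate 2. The other lay at 18373194, 456 bp from the TSS of gl, with a signal value of 128.8, and was not among the 4809 strongest peaks of replicate 1 (rank 9165) nor among the 2404 strongest optimal peaks. Another summit, at 18375141, outside the extended span and 2403 bp from that TSS, had a signal value of 291.3; it was chosen after its value was seen.

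The first question was how far the replicates found the same peaks. Of the 4809 strongest peaks of replicate 1, 63.6% had a summit within 200 bp among the 4809 strongest of replicate 2, against 1.44% ± 0.194 (SD) in 1000 circular shifts (permutation p = 0.001, the smallest that the shifts can give). The shifts do not keep the closeness of peaks to TSSs. This comparison therefore does not separate agreement at particular sites from a preference for TSSs common to both replicates. The share was similar from the 500 strongest peaks (64.4%) to all 30000 entries (59.7%). The strongest optimal peaks were strong in both: the peak in an intron of dnr1 ranked 3 in replicate 1 and 1 in replicate 2, and that at Cat, the gene of catalase, ranked 2 in both. Other peaks differed. The strongest peak at Mef2, a regulator of muscle development, ranked 836 in replicate 1 and had no entry within 200 bp in replicate 2, and that at cry, which encodes cryptochrome, ranked 636 and 3753. Across the 4680 optimal peaks with an entry in both lists, the signal values had a Spearman rho of 0.437 (95% bootstrap interval 0.414 to 0.458) and a Pearson r of 0.541 on the log10 scale, across peaks, which are not independent replicates. The optimal peaks were the strongest entries of the pooled list, so these correlations hold for peaks chosen by pooled signal and not for all entries.

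**Figure D1:**
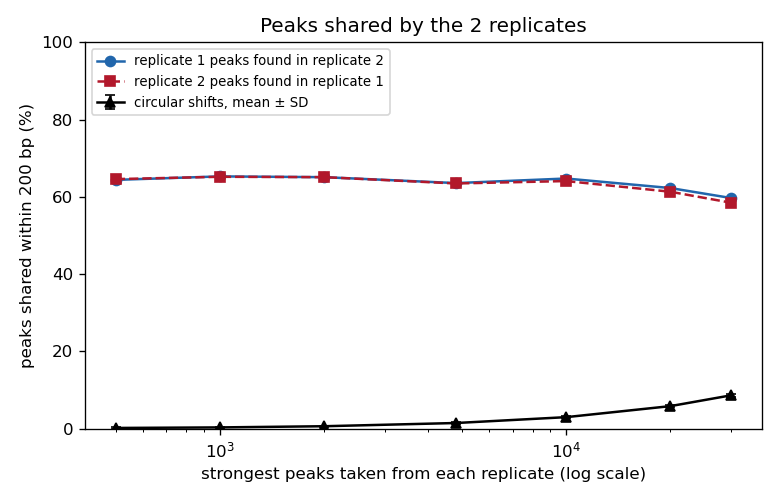
Percentage of the strongest peaks of each replicate (vertical axis) that had a summit within 200 bp among as many of the strongest peaks of the other replicate, against the number of peaks taken (horizontal axis, log scale), with the mean and SD of 1000 circular shifts. The share was 63.6% at 4809 peaks, where shifts gave 1.44%.

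The next comparison was of the position of the peaks with the annotation. Peaks were concentrated near TSSs: 2238 of 4809 summits (46.5%, 95% Wilson interval 45.1 to 47.9) lay within 1 kb of a TSS of a protein-coding gene, 2.29 times the 20.3% ± 0.985 (SD) of 1000 circular shifts (permutation p = 0.001, the smallest possible). The share was 47.0% ± 3.68 (SD, n = 2) over the strongest peaks of the replicates. Of the remaining summits, 1721 lay in introns (35.8% of all peaks, against 36.3% in shifts) and 772 outside protein-coding genes (16.1%, against 28.3%). Coding exons more than 1 kb from a TSS held 31 summits (0.645%, against 10.9%). The shift values for introns, coding exons and positions outside genes came from a separate set of 100 shifts. Peaks at TSSs were about as high as the others, with medians of 202.1 and 199.1 and a ratio of 1.02 (permutation p = 0.457, 100000 resamples); among the 2404 strongest peaks the ratio was 1.07 (permutation p = 0.00258).

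The strongest peak (signal value 3648) lay on 2R from 22569702 to 22570542, in an intron of dnr1. The peak at Cat (3L 18822604 to 18823184, signal value 3268) lay in an intron, 312 bp from a TSS. The third (2R 9138096 to 9138743, signal value 2740) lay between genes, 106 bp from the TSS of CG8788. Among the other strong peaks, those at CG13204, larp, yip2, CG11050, jumu, a forkhead gene, and puc, which encodes a phosphatase acting on JNK, lay in introns. The peaks nearest to Ugalt, Ntf-2r, CG14100 and CG43389 lay outside genes, and CG32772 had peaks in its 5′ UTR and an intron, both among the 15 strongest. Genes with the most summits were long: sbb had 25 over 79.1 kb, kirre 20 over 394.1 kb, Tet 19 over 93.0 kb, Eip75B 18 over 113.7 kb and shn 18 over 58.3 kb. CG1677 had 16, Raf and Svil 15 each, and psq and bun 14 each.

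The density of peaks on X was close to that on the large autosomes. X held 36.4 peaks per Mb and 2L, 2R, 3L and 3R together 36.1, a ratio of 1.01 (95% exact interval 0.934 to 1.08, exact binomial p = 0.865). The ratio was 1.03 and 0.968 in the strongest peaks of replicates 1 and 2. In the full list of replicate 1, a comparison chosen after seeing the data, it was 1.12 (exact binomial p = 3.13e-15), and in that of replicate 2 it was 0.993. Chromosome 4, which was not part of the comparison, held 16 peaks, 11.9 per Mb.

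Genes of signalling and of the ribosome were bound more often than genes of the same length, and neuronal genes less often; the lists of eye genes were not. Of 23 genes of Notch and EGFR signalling, 17 were bound, against 8.16 ± 2.10 (SD) in length-matched lists (permutation test, adjusted p = 0.00065). Among them the strongest peaks lay in introns of pnt, an ETS factor downstream of EGFR (signal value 1501, rank 32), Egfr, the receptor (1053, rank 88), and Delta, a Notch ligand (703.7, rank 223). Of 88 ribosomal protein genes, 57 were bound, against 13.2 ± 3.33 (permutation test, adjusted p = 0.00065), with 54 in replicate 1 and 60 in replicate 2. Their strongest peaks were at RpL31 (760.3), RpS19b (599.2) and RpS4 (424.8). The summits counted for RpL31 and RpS19b lay outside these genes, in introns of other genes, 1694 and 908 bp from the TSSs of RpL31 and RpS19b. The median of the ribosomal list, 205.7, was at percentile 48.9 of length-matched lists of bound genes, with 8.34 in replicate 1 and 75.1 in replicate 2. Of 20 neuronal genes 3 were bound, namely elav, ChAT and Rbp9 (which had no summit among the strongest peaks of replicate 2), against 9.71 ± 2.18 (permutation test, adjusted p = 0.0104); the fold of 0.309 became 0.601 with the span extended by 5 kb and 0.646 without matching on length, which ended the call, and when only summits within 1 kb of a TSS of the gene counted the fold was much the same, 0.322, but no longer past the threshold (permutation test, adjusted p = 0.163).

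Of 27 genes of retinal specification, 8 were bound, against 11.3 ± 2.5 in length-matched lists (permutation test, adjusted p = 0.433). These were so, a homeodomain gene of the eye determination network (signal value 759.0, rank 179), hth (501.5), salr (396.4), dac, svp, oc, B-H2 and gl. The median signal at these genes was 249.5, at percentile 34.5 of length-matched lists of bound genes. The strongest peak counted for so lay inside that gene but 10001 bp from its nearest TSS, and within 1 kb of a TSS of another gene. Of 33 genes of phototransduction and the rhabdomere 9 were bound, against 10.7 ± 2.51 (permutation test, adjusted p = 0.663), with the strongest peaks at norpA, the phospholipase C of phototransduction (609.6), rdgC (341.4) and cry (330.8). Of 18 genes of lens, cone and pigment cells 8 were bound, against 6.97 ± 1.94 (permutation test, adjusted p = 0.663), among them kirre (596.7), ct (474.2) and sv (398.7).

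Of 23 genes of the ecdysone response, 15 were bound, against 9.99 ± 2.25, which did not pass the correction (permutation test, adjusted p = 0.0874). The peaks at Eip93F (1273), the nuclear receptor gene Hr4 (991.2) and Eip78C (849.0) were strong, and the median of the list, 503.9, was at percentile 99.3 of matched lists; it was at 84.6 in replicate 1 and 99.5 in replicate 2. Of 20 body patterning genes 12 were bound (expected 10.1, permutation test, adjusted p = 0.663), with dpp (1049), Antp (479.8) and ptc (309.9) highest, and the median was low, at percentile 3.61, with 1.16 in replicate 1 and 6.83 in replicate 2. Glia had 6 of 14 (expected 4.58, permutation test, adjusted p = 0.663), with loco at 1150, moody at 395.8 and wrapper at 262.5. Muscle had 5 of 22 (expected 8.09, permutation test, adjusted p = 0.362), with Mef2 at 315.4, Zasp52 at 297.9 and sls at 223.4. Fat body and blood cells had 3 of 14 (expected 3.93, permutation test, adjusted p = 0.758), namely srp, Lsp1gamma and Lsp2. The germ line list had 3 of 21 (expected 4.14, permutation test, adjusted p = 0.663), namely dhd, topi and bgcn, the last without a summit among the strongest peaks of replicate 1. The median of the germ line list was also low, at percentile 4.785, with 6.795 in replicate 1 and 17.9 in replicate 2. The summits counted for wrapper, Lsp2 and topi lay outside these genes, 3246, 2723 and 2997 bp from their TSSs. Each was within 1 kb of a TSS of another gene. Cuticle proteins had 6 of 70 (expected 11.1, permutation test, adjusted p = 0.235), with Cpr72Ea and Cpr72Eb sharing a peak of 323.4 and Cpr51A at 241.3; fewer were bound past the threshold with the span extended by 5 kb (fold 0.527, permutation test, adjusted p = 0.013) and without matching on length (0.371, adjusted p = 0.00858).

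**Figure D2:**
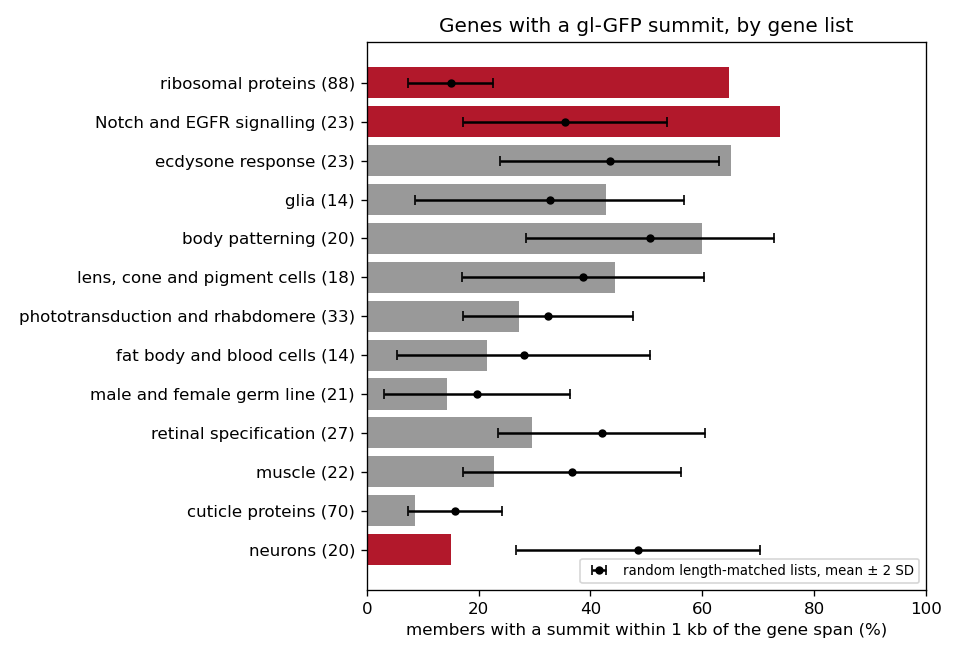
Percentage of the members of each gene list with a summit within 1 kb of the gene span (bars, number of members in parentheses; red bars have an adjusted p under 0.05), with the mean of 10000 random length-matched lists and 2 SD (points and lines). Ribosomal proteins (64.8%) and Notch and EGFR signalling (73.9%) lie above their random lists and neurons (15%) below.

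The last comparison was of the sequence at the summits with that of the flanks. The test called 9 6-mers. At an adjusted p under 0.05 and any fold, 166 6-mers were more frequent at the summits and 315 less frequent, 176 of these by 1.5 or more. AGAGAG was at 9.63% of the summits and 5.53% of the flanks (fold 1.74, exact McNemar test, adjusted p = 9.56e-12), followed by ACTGAG (1.60), AGAGCG (1.59), TACTAA (1.59), GTACTA (1.56), GAGAGA (1.56), AAGTCC (1.55), GAGAGC (1.53) and GTGCAC (1.52). Among the 2404 strongest peaks TACTAA was the only one of the 9 still called, and AGAGAG was at 1.28 (exact McNemar test, adjusted p = 0.0668). AGAGAG was at 2.07 at peaks within 1 kb of a TSS and 1.33 at the others (exact McNemar test, adjusted p = 0.0522). At the others it was called with flanks at 800 bp (1.56, exact McNemar test, adjusted p = 0.00228). The tests by distance from a TSS were chosen after seeing the data. Of the fixed motifs, GAGAGA, bound by the GAGA factor, was called, with a fold of 1.15 in replicate 1 (exact McNemar test, adjusted p = 0.152) and 1.73 in replicate 2, and it was not called among the 2404 strongest peaks (1.31). The others were not called: the folds were 0.855 for CAGGTA of Zelda, 1.03 for TATCGA of DREF, 0.647 for the E-box CACGTG, 1.10 for TGACTC of AP-1, 0.836 for TAATTA of homeodomains and 1.03 for AGATAA of GATA factors. No recognition sequence of Glass was among the fixed motifs, so none was tested by name. The replicates differed in the 6-mers at their summits: AGAGAG had a fold of 1.31 in replicate 1 and 1.85 in replicate 2, and TACTAA 1.91 and 0.917. AGATAA, near 1 in the optimal list, was more frequent at the summits of replicate 1 (1.25, exact McNemar test, adjusted p = 0.0115) and less frequent at those of replicate 2 (0.748, exact McNemar test, adjusted p = 0.00536). TAATTA was less frequent at the summits of replicate 2 (0.636, exact McNemar test, adjusted p = 1.23e-05), and CAGGTA (0.705) and CACGTG (0.576) at those of replicate 1 (exact McNemar test, adjusted p = 0.0204 and 0.0233). The strongest peaks of replicate 1 gave 115 called 6-mers and those of replicate 2 gave 55, and 1 of the 9 was called in both, so the list of called 6-mers is not stable between replicates.

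**Figure D3:**
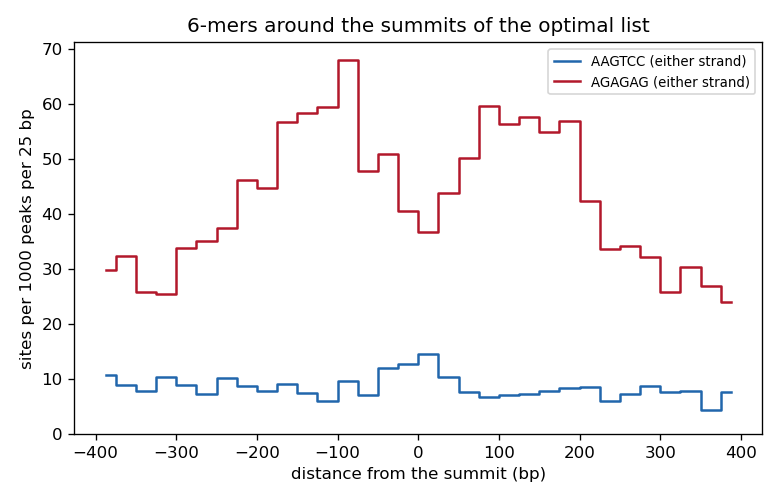
Sites of AGAGAG and AAGTCC on either strand per 1000 peaks in bins of 25 bp (vertical axis) by distance from the summit in bp (horizontal axis). AAGTCC was highest just after the summit (14.6 sites), whereas AGAGAG had 36.8 sites there and its highest value, 68.0, in the bin that starts 100 bp before the summit. On the other side AGAGAG rose again, to 59.7 in the bin that starts 75 bp after the summit, so it was more frequent beside the summit than at it.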

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

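All tests of CAAAGTCC in this part were chosen after the result was seen.

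Entries of the pooled list outside the optimal list, which no comparison above uses, also carried signal. Of these, 1481 had the highest −log10 q value of the pooled list, as all optimal peaks did. The 8-mer CAAAGTCC lay within 50 bp of the summit in 151 of the 25191 entries outside the optimal list, against a mean of 66 in flanks 500 bp away (fold 2.29).

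In the optimal list CAAAGTCC was at 94 summits and at a mean of 10.5 flanks (fold 8.95). It was found by 6 searches, over k-mers of 4 lengths in all peaks, where 8-mers were ranked by 2 scores, and over 8-mers in 2 subsets, in which 762752 k-mers were looked at in total; the exact binomial p multiplied by that number was 1.28e-20, but no independent data were used. Base composition is argued against by the median fold of 0.885 for other 8-mers of the same composition. Promoter sequence is argued against by the fold of 8.91 at peaks more than 1 kb from a TSS (exact binomial p = 1.86e-14, without allowance for the search). That subset was 1 of the 2 searched, so its fold is not independent of the choice of the 8-mer. Presence in 1 replicate only is argued against by the lower of the replicate folds, 3.53 in replicate 1 against 12.1 in replicate 2. The replicates were unequal, with the 8-mer at 53 of the 4809 strongest summits of replicate 1 and 115 of replicate 2. A larger part from replicate 2 stays open. The 8-mer was chosen in a list made from both replicates, so neither fold is independent of the choice. The base after the 8-mer was A at 74.2% of the sites, as in the element known for the HNF4 family of nuclear receptors, so occupancy by such a factor may be considered, but data on binding of Hnf4 were not used here and it cannot be told apart from other causes. No biological explanation was tested against a group of the design.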

How the results depend on the processing

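The full replicate lists for X, the 6-mers at TSSs, away from them (with 3 choices of peaks and flanks) and among the 1000 strongest peaks, and matching on TSS count were tests chosen after seeing the data. The share of peaks at TSSs and the replicate overlap kept their direction and their side of the threshold under all alternatives (36.6% to 58.1% and 58.3% to 68.1%). The 3 called lists were called in each replicate and among the 2404 strongest peaks; without matching on length 5 lists were called, 2 of them in common, with ecdysone response and body patterning (more bound) and cuticle proteins (fewer, as with 5 kb) gained. The count of 6-mers was unstable: 9 became 38 among the stronger peaks, 25 with windows of 100 bp, 16 with flanks at 1000 bp, 28 at peaks more than 1 kb from a TSS, 37 at these with flanks at 800 bp, 24 at the 800 strongest of them, none of which was among the 9, 47 among the 1000 strongest, and 55 to 115 when a replicate was left out. Of the 9, 1 was still called among the stronger peaks, 5 away from TSSs and 0 among the 1000 strongest; the cause was not tested. The correlation of the replicates was 0.473 with summits within 100 bp. The ratio of signal at TSSs was 1.07 among the stronger peaks and 0.979 with 500 bp. The X ratio was 0.968 to 1.03 when a replicate was left out, 0.972 away from TSSs, 1.12 in the full list of replicate 1 and 0.993 in that of replicate 2. The percentile of retinal genes was 57.4 without matching.

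Of the values below, those past the threshold were AGATAA without either replicate, TACTAA and CAGGTA without replicate 2 and TAATTA without replicate 1. Fold of bound members without matching was 1.28 for retinal specification and 1.18 for phototransduction; leaving out a replicate gave 0.871 to 1.13 for lens, cone and pigment cells and 0.901 to 1.26 for glia, the lower values without replicate 2; for body patterning it was 0.843 among stronger peaks and 0.935 at TSSs, and for the germ line 1.11 with 5 kb. With a replicate left out the fold at summits was, without replicate 1 and without replicate 2, 0.917 and 1.91 for TACTAA, 1.01 and 0.705 for CAGGTA, 0.873 and 0.928 for TATCGA, 1.11 and 0.759 for TGACTC, 0.636 and 1.06 for TAATTA, and 0.748 and 1.25 for AGATAA. Among stronger peaks it was 0.986 for AGAGCG, 0.932 for TATCGA and 0.938 for TGACTC, and among the 1000 strongest 0.905 for AGAGCG, 0.871 for GAGAGC, 1.1 for CACGTG, 0.821 for TGACTC and 1.01 for TAATTA. It was 1.03 for CAGGTA with flanks at 1000 bp, 0.959 for GTACTA and 0.853 for TATCGA near TSSs, and 0.940 for TGACTC away from them, where it was also 0.792 for TATCGA with flanks at 800 bp and, among the 800 strongest, 0.983 for AGAGAG, 0.958 for TATCGA and 0.869 for AGATAA; the cause was not tested. Overlap and correlation need both replicates, so neither could be computed without one. The pooled list gave the same peaks and tests nothing.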

Other observations

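The lists of fatty acid oxidation and glycolysis and both tests of the unshared peaks were chosen after seeing the data; the tests of the ribosomal protein genes were set before their values were seen, except the comparison of tRNA genes with protein-coding genes, which was chosen after.

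Genes of fatty acid oxidation were bound often. The list of 16 genes was written after peaks had been seen at 8 of them, whd, colt, Arc42, Mtpalpha, Mtpbeta, Echs1, scu and yip2, so only the other 8 give a test. That test uses the peak list from which the pathway was picked, so it is not independent of the choice. Of those, 7 were bound, namely CPT2, Mcad, Etf-QO, wal, CRAT, Acox57D-p and Acox57D-d, against 1.69 ± 1.15 (SD) in length-matched lists (permutation test, p adjusted over 2 lists 0.0002), with 6 in replicate 1 and 7 in replicate 2. CAAAGTCC was at a summit of 7 of the 8 genes seen before and of CPT2 alone among the others. The 7 are at some of the strongest peaks with CAAAGTCC, so this count may only reflect how they were first seen. Of 12 glycolysis genes 8 were bound, against 3.0 ± 1.5 (permutation test, adjusted p = 0.0032), among them Hex-A, Pgi, PyK and Ldh.

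Ribosomal protein genes were bound 4.31 times as often as length-matched genes. Crowding of neighbouring genes as the whole cause is argued against by the fold of 3.16 after matching also on the number of TSSs. That matching used 30 strata of length and TSS count, so crowding within a stratum was not covered. The fold was lower than without it, and a part played by crowding stays open. A restriction to weak peaks is argued against by the fold of 4.53 among the 2404 strongest. Of 290 tRNA genes, which another polymerase transcribes, 32 had a summit within 500 bp, against 10.6 ± 4.34 (SD) in shifts (fold 3.02, permutation p = 0.002). The 95% interval around that fold, 2.22 to 3.83, reflects the SD of the shifts only. However, protein-coding genes had a summit within 500 bp of their outermost TSS 3.33 times as often as in shifts. The tRNA fold met the bound set beforehand for non-specific recovery at highly transcribed genes. By the comparison with protein-coding genes, chosen afterwards, the tRNA genes did not stand out from other genes. Non-specific recovery therefore stayed open and cannot be told apart from other causes of binding at the ribosomal protein genes. The shared control alignment was not analysed here.

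The replicates shared 63.6% of their 4809 strongest peaks. Ranking noise had been set to need over 80% of the unshared peaks of replicate 1 in the full list of replicate 2; the share was 79.1% (95% Wilson interval 77.1 to 80.9), and in the other direction 84.2% (82.5 to 85.9), so the values lie on either side and this explanation cannot be told apart from its absence. By the bound alone the first value would have counted against it; the use of the interval was chosen after the value was seen. The unshared peaks of replicate 2 lay within 1 kb of a TSS more often than those of replicate 1 (52.2% against 38.6%, a difference of 13.6 percentage points), but the TSS shares of the whole lists, 49.6% and 44.4%, already imply a difference of 14.2, so a different mix of sites as the cause was left open. With 1 group no biological explanation was tested.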
